A study of Populus trichocarpa and Populus trichocarpa
Laccaria bicolor and Laccaria bicolor with 7 samples.

How the data were processed

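RNA of 7 libraries was analysed, 1 per group: free-living mycelium of Laccaria bicolor strain S238N, and control roots and mycorrhizal root tips of Populus trichocarpa clone 101-74 at 2, 4 and 12 weeks of contact. Groups and weeks were taken from the sample titles and characteristics in the labels; the growth protocol names the last sampling as 2 weeks, where titles and characteristics give 12. Per the labels, control roots were fine lateral roots and mycorrhizal samples were short colonised roots, so tissue type and colonisation differ together. Per the labels, 4 RNA preparations were pooled per library and amplified with a SMARTer cDNA kit, and each library was read as 37-base Illumina GAIIx sequences in a lane of its own. How the mycelium was grown is not given in the sources used here.

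The 10 deposited files hold, per the file headers, the model length, unique gene reads, total gene reads and RPKM of every gene model, separately for poplar and Laccaria. Counts of unique and of total reads were deposited by the authors as whole numbers. RPKM values deposited by the authors equalled total reads per kilobase of model over the total reads of that organism to within 0.0005. The aligner, the counting tool and the treatment of reads that hit several models are not given in the sources used here. Poplar files list 73013 transcripts of 41335 loci and Laccaria files 23130 models. Between 38.6 and 41.6% of poplar reads and between 90.7 and 92.2% of Laccaria reads were unique. In the 27082 poplar loci with a single transcript, 80.4 to 85.5% of reads were unique. Much of the poplar rest is thus shared between isoforms of the same locus, which summing per locus removes. Among pairs of poplar isoforms of equal length with no unique reads, 3 to 5 of 71 to 111 pairs per library had equal totals, and the median difference was 0.640 to 0.901 times the square root of the sum. Differences of that order arise when each shared read is assigned at random, so each read was taken as counted once. Laccaria counts of control roots and poplar counts of mycelium were not used here, so the background of reads assigned to the absent partner was not measured.

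The main values were total reads, summed over the isoforms of a poplar locus. Loci are named by their IDs as the files give them. None of the 41335 poplar loci matched the table of gene names used (0 matches), and no such table was used for Laccaria. Gene lists fixed beforehand by words in product names could therefore not be tested. Named genes followed a rule fixed before the data were examined. With no products known, it allowed at most 2 IDs that rose and 2 that fell per organism, those of largest change past the threshold and with at least 5 CPM in the higher tissue, or of lowest p where none passed. It added the Laccaria IDs of MiSSP7 and MiSSP8 and 7 IDs listed as aquaporins, of which 4 were present in the files; these names come from memory of the genome's annotation, and neither the files nor the table of gene names could check them. Other features named were chosen after their values were seen.

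Tests used edgeR 4.0.16 in R 4.3.3: quasi-likelihood fits on total reads with TMM scaling, the filterByExpr filter, two-sided p and Benjamini-Hochberg adjustment, with a threshold of 0.05. Poplar root tips were compared with control roots over 3 weeks with the week as a block, leaving 2 residual degrees of freedom. A call thus means a mean difference that is large against its spread over the 3 weeks, and not that the weeks are alike. The test draws the spread of each gene toward that of other genes, so calls rest partly on this pooled spread. Change with time was the interaction of tissue with log2 weeks, with 1 residual degree of freedom. The 3 Laccaria root tip libraries were compared with the lone mycelium library, which was assumed to vary like the others (2 degrees of freedom), and change with log2 weeks was fitted within root tips (1 degree of freedom). The p-values measure spread between weeks and not between plants. For single weeks no test exists; ratios of TMM-scaled counts, expressed as counts per scaled library size (CPM), were used, with a rule of at least 4-fold change and at least 20 reads in the pair, for which counts under 3 were raised to 3. Ratios of named genes used the reads as counted, with exact conditional binomial intervals, and a count of 0 alone was replaced by a limit of 3 reads per library and gave a bound.

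Correlations across loci used log2 of CPM plus 0.5 over 19709 loci with a mean of at least 5 CPM; loci are not independent replicates. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, unique reads, limma 3.58.1 on log2 RPKM plus 1 or 0.1, no week block, a linear week, leaving out each week, library totals, and other read and fold minimums. Fits without the 2 Laccaria models with most mycelium reads, and the alternatives for correlations, were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

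Each fit was tested on simulated counts with known changes in 200 genes. All genes were drawn with the same spread between libraries, and changes were placed only in genes with higher mean counts. Recovery in the real data can thus be lower. Across weeks in poplar (28996 genes), 51 of 100 changes of 4-fold and 100 of 100 of 16-fold were recovered, with 4 false among 155 calls. For Laccaria against mycelium (11045 genes) the recovery was 0 and 14 of 100. For change with time it was 0 and 8 of 100 in poplar (28996 genes) and 0 and 0 of 100 in Laccaria (7252 genes). Simulated changes with time reached their full size at 12 weeks and grew by less than that from 2 weeks.

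Depth limits what the root tips can show of the fungus: a limit of 3 reads equals 0.440 scaled CPM in mycelium but 1.81, 0.549 and 3.36 in root tips at 2, 4 and 12 weeks.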

Results

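Ectomycorrhiza is a symbiosis in which a fungus sheaths short roots of a tree and grows between their outer cells. RNA was sequenced from roots of the black cottonwood Populus trichocarpa colonised by the basidiomycete Laccaria bicolor, after 2, 4 and 12 weeks of contact. Each time point had 1 library of mycorrhizal root tips and 1 library of control roots, the latter being fine lateral roots of plants grown without inoculum. One further library came from free-living mycelium of the fungus, which made 7 libraries in all. Every library was a pool of 4 RNA preparations and had no replicate, so a difference at a single time point has no replicate check.

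Total reads assigned to poplar genes were 19695507, 21314880 and 19216311 in control roots at 2, 4 and 12 weeks. In mycorrhizal root tips they were 17253295, 17448454 and 6430464, so that the 12-week root tip library was the shallowest. Reads assigned to Laccaria models came to 16952961 in free-living mycelium and to 1389175, 3216040 and 741462 in root tips at 2, 4 and 12 weeks. Intervals of shares and of ratios between libraries, and limits for counts of 0, are at the 95% level and cover counting error only, because amplified reads are not independent molecules.

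**Figure D1:**
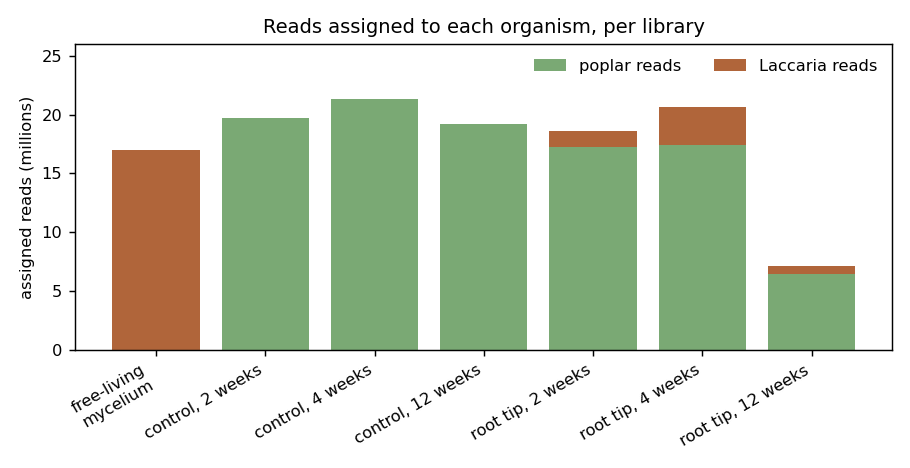
Bars give reads assigned to poplar (green) and Laccaria (brown) in each of the 7 libraries, from 0. The 12-week root tip library holds 6430464 poplar reads and 741462 Laccaria reads, fewer than any other root tip library.

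The first comparison asked how much of the root tip transcriptome was fungal. Laccaria took 7.45% of assigned reads in root tips at 2 weeks (Wilson interval 7.44 to 7.46%), 15.6% at 4 weeks (15.5 to 15.6%) and 10.3% at 12 weeks (10.3 to 10.4%). The fungal share was thus highest at 4 weeks and lowest at 2 weeks in these 3 libraries, with differences far beyond counting error. Counting unique reads only raised the shares to 15.2, 30.6 and 20.1%. That setting leaves out more poplar reads, of which 38.6 to 41.6% were unique in root tips, against 90.7 to 92.2% for Laccaria. Leaving out the 10 most abundant genes of each organism lowered the shares to 4.15, 12.0 and 6.33%. Without the 2 Laccaria models that had most mycelium reads they were 4.54, 12.6 and 7.60%, a setting added after the data were seen. The order of the weeks was the same under these 3 settings. Without replicate libraries, variation between pools at one age is not covered by these intervals.

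The second comparison asked which fungal genes differ between root tips and free-living mycelium. MiSSP7, a small secreted effector protein of Laccaria that enters poplar cells and stabilises a repressor of jasmonate signalling, is reported here as the model of 279 bases listed beforehand under that name. It had 3 reads in mycelium against 636, 2572 and 250 reads in root tips at 2, 4 and 12 weeks. After scaling, this was 875-fold higher at 2 weeks (counting interval 298 to 4254), 1070-fold at 4 weeks (366 to 5193) and 637-fold at 12 weeks (216 to 3110). MiSSP8, a second small secreted protein of the fungus, was listed likewise as the model of 334 bases; the files carry no names to check either. It had 0 reads in mycelium and 133, 130 and 15 reads in root tips, which is at least 183-fold, 54.1-fold and 38.2-fold higher against a floor of 3 reads in the mycelium library. Across the 3 root tip libraries the log2 difference of MiSSP7 was 9.64 with a standard error of 1.95, and its adjusted p over all genes was 0.102 in edgeR's quasi-likelihood test. The adjusted p of MiSSP8 was 0.119. Both were listed by name as proteins of this symbiosis and not at random. Adjusting over the list of 2 alone would thus give no independent support for a difference.

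Among 7 model IDs listed beforehand as Laccaria aquaporins, membrane channels for water and small solutes, 4 were present in the files, and the files carry no names against which to check the list. The listed model of 993 bases had 14 reads in mycelium and 362, 685 and 36 reads in root tips, or 107-fold (62.8 to 197), 61.1-fold (36.1 to 112) and 19.7-fold (10.3 to 39.5) higher. Its adjusted p was 0.210 over all genes and 0.00916 adjusted over the list alone, where 1 of 3 tested members passed, against 0 of 3 over all genes. The one of 999 bases was 23.7-fold higher at 4 weeks (11.2 to 60.1), but stood at 0.590 and 1.09 times the mycelium level at 2 and 12 weeks, where 1 read each left a difference not detectable; its adjusted p was 0.718. The one of 939 bases had 56 reads in mycelium and 5, 19 and 2 reads in root tips, 2.71-fold (1.10 to 8.68), 2.36-fold (1.38 to 4.21) and 3.66-fold (0.968 to 31.0) lower, with an adjusted p of 0.829 and a log2 difference whose sign flipped when log2 RPKM values were tested instead. The one of 1047 bases had 1 read or none in every library and was not tested.

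**Figure D2:**
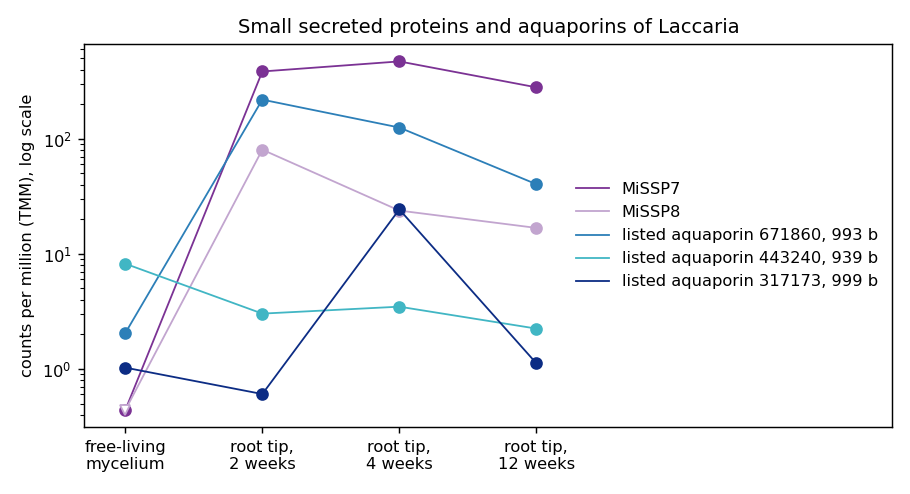
Points give TMM-scaled CPM, on a log axis, of MiSSP7, MiSSP8 and 3 models listed as aquaporins in the mycelium library and the 3 root tip libraries, with lines joining the points of 1 gene. The open triangle marks MiSSP8 in mycelium, with 0 reads, drawn at the limit of 3 reads; MiSSP7 goes from 0.440 in mycelium to 385, 470 and 280 in root tips.

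Over all 11045 Laccaria models tested, 9 fell in root tips and 0 rose at an adjusted p under 0.05 in edgeR. The 9 models were lower at all 3 weeks, by fitted log2 differences from −11.31 to −6.13, which depend on the prior count where root tips had no reads. Model 671638 had 18913 reads in mycelium and 17, 25 and 18 in root tips, which is 270-fold (168 to 463), 606-fold (410 to 937) and 137-fold (86.9 to 232) lower, with an adjusted p of 0.0459. Model 295242 went from 3272 reads to 0, 0 and 1, at least 264-fold and 874-fold lower at 2 and 4 weeks, and 428-fold lower at 12 weeks from 1 root tip read (76.8 to 16908), with an adjusted p of 0.0381. On the higher side the models of lowest p were 451828 and 453936, neither past the threshold (adjusted p 0.0570 and 0.102). Model 451828 had 0 reads in mycelium and 157, 378 and 101 in root tips, at least 216-fold, 157-fold and 257-fold higher. Model 453936 had 0 reads against 333, 307 and 43, at least 458-fold, 128-fold and 110-fold higher.

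The lone mycelium library was assumed to vary as the root tips do, which left 2 residual degrees of freedom. The balance of higher and lower models depended on the scaling. The median log2 difference of root tips from mycelium was 0.22 in edgeR, and 1.27 and 1.56 with limma on log2 RPKM plus 1 and 0.1. At an unadjusted p under 0.05 there were 588 higher and 382 lower models, 970 together, where chance alone gives 552, and DESeq2 called 320 higher and 92 lower. Leaving out the root tip library of 2 weeks gave 22 higher and 29 lower models, that of 4 weeks 178 and 98, and that of 12 weeks 0 and 0. Without a filter the counts were 145 and 106, while limma on log2(RPKM + 1) gave 116 and 4.

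A pair of models took most fungal reads in mycelium. Model 477251, of 276 bases and singled out after its values were seen, took 61.8% of fungal reads in mycelium, and 38.4, 18.9 and 25.1% in root tips at 2, 4 and 12 weeks. Model 710288, of 1431 bases and singled out likewise, took 16.5% in mycelium. Whether either model is a messenger RNA was not checked here, since no sequence was used. All other models shared 3686799 mycelium reads. At single weeks, 625 models were at least 4-fold higher and 641 at least 4-fold lower in root tips at 2 weeks, 2077 and 1373 at 4 weeks, and 997 and 1095 at 12 weeks, among 9768, 11404 and 9553 models with at least 20 reads in the pair. Scaled by library totals alone, the counts were 2910 and 115, 5849 and 158, and 2976 and 223, and the median log2 difference went from −0.21, −0.02 and −0.24 to 1.36, 2.06 and 1.35. With the 2 models left out of those totals, a setting added after the data were seen, the counts were 686 and 549, 2350 and 1129, and 908 and 1261. These 3 sets share the mycelium library and were not compared with each other.

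The third comparison asked which poplar genes differ between mycorrhizal root tips and control roots at every stage. Of 28996 loci tested with the week as a block, 17 rose and 1 fell in mycorrhizal root tips at an adjusted p under 0.05 (edgeR). Loci at an unadjusted p under 0.05 in the same test numbered 848 higher and 457 lower, 1305 together, where chance alone gives 1450. Small p-values were thus not in excess over all loci. The 17 loci were higher at 3 of 3 weeks. The fitted log2 differences of the 17 loci lay from 3.36 to 10.41, the highest of them in loci near 0 reads in control roots, where the fit depends on its prior count. Potri.010G000200 had 0, 18 and 24 reads in control roots and 482, 12258 and 1248 in root tips at 2, 4 and 12 weeks. It was at least 208-fold higher at 2 weeks, 909-fold higher at 4 weeks (575 to 1535) and 176-fold higher at 12 weeks (118 to 276), with a log2 difference of 8.89 ± 0.81 (SE) and an adjusted p of 0.0128. Potri.007G083300 had 0, 0 and 1 reads in control roots against 125, 1641 and 35, at least 53.8-fold and 731-fold higher at 2 and 4 weeks, and 119-fold higher at 12 weeks from 1 control read (19.9 to 4814), with an adjusted p of 0.0128. Only 29, 238 and 6 of its root tip reads were unique. Reads shared between isoforms of a locus also count as not unique, so how many were shared with similar loci is not known. Its level is uncertain to that extent. Potri.015G101700, the locus that fell, had 237, 90 and 7 reads in control roots and 1, 1 and 0 in root tips, or 183-fold (32.6 to 7278) and 67.4-fold (11.8 to 2691) lower at 2 and 4 weeks from 1 root tip read each, with an adjusted p of 0.0399. Its difference at 12 weeks was not detectable at this depth.

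The test had 2 residual degrees of freedom and the counts moved with single weeks: 253 higher and 13 lower without week 2, 0 and 0 without week 4, and 35 and 2 without week 12. DESeq2 called 143 and 19, unique reads 6 and 0, limma on log2(RPKM + 1) 1 and 0, and a model without the week block 0 and 0.

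The 200 poplar loci of lowest p on each side of the test lay side by side in the genome more often than random tested loci. Only 17 loci on the higher side and 1 on the lower passed the threshold, so most of the 200 were not called. The random sets were not matched for neighbouring copies and no other contrast was ranked, so the grouping cannot be tied to mycorrhiza. Among the 200 loci of lowest p on the higher side, 36 pairs lay within 3 loci of each other, against a mean of 3.10 in 10000 random sets of 200 loci (one-sided permutation p = 0.0001, the smallest these sets can give). Among the 200 on the lower side there were 9 pairs against 3.12 (permutation p = 0.0043). With unique reads alone there were 17 pairs on the higher side, against 3.18, and 11 on the lower side, against 3.16. Over these 4 comparisons the Benjamini-Hochberg adjusted permutation p ran from 0.0002 to 0.0043. The densest group was a run of 20 loci on chromosome 7 around Potri.007G083300, with chromosome and order read from the IDs, and it was singled out after its values were seen. Of these, 10 were tested, 6 were among the 200 and 3 rose in the test over all weeks. Together the 20 loci held 46.4, 16.1 and 9.76 CPM in control roots at 2, 4 and 12 weeks, and 52.6, 394 and 75.9 in root tips. The locus next to Potri.007G083300, which was not called, held 866 of the 963 control reads at 2 weeks and was lower in root tips there (266 reads), whereas the 3 loci that rose had 0 to 4 reads in each control library. Only 161 of 845, 850 of 7011 and 60 of 432 root tip reads there were unique.

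The fourth comparison asked how the poplar difference moved with time. In 804 loci the log2 difference between root tips and control roots grew with each doubling of contact time, and in 360 it fell (edgeR, adjusted p under 0.05, 28996 tested). At single weeks, root tips had 565 loci at least 4-fold higher and 670 at least 4-fold lower at 2 weeks, 596 and 357 at 4 weeks, and 995 and 304 at 12 weeks, among 27628, 28407 and 26355 loci with at least 20 reads in the pair. A set of 221 loci was at least 4-fold lower in root tips at 2 weeks and at least 4-fold higher at 12 weeks, where independent lists would share 17.7, and 33 loci went the other way against 4.21. At both weeks 62 loci were at least 4-fold higher, against 13.6, and 4 at least 4-fold lower, against 5.51. In the 221 loci the median level in control roots went from 23.3 CPM at 2 weeks to 11.3 and 2.23 at 4 and 12 weeks, while in root tips it went from 2.61 to 16.6 and 47.3.

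A smaller set moved one way throughout. At least 4-fold higher in root tips at all 3 weeks were 36 loci, against 0.184 for independent lists, and 0 loci were at least 4-fold lower at all 3, against 0.0393. At 12 weeks the limit of 3 reads equals 0.527 CPM in root tips but 0.156 in control roots. That limit alone made a 4-fold fall harder to reach there than a 4-fold rise. The minimum of 20 reads in the pair acts the other way, since each read stands for more CPM in root tips. Which direction the rule favoured at that week was thus not settled. With at least 100 reads in the pair, 646 loci were higher and 142 lower in root tips at 12 weeks. The median of the 36 loci was 0.193, 0.904 and 1.17 CPM in control roots and 9.14, 40.6 and 27.3 in root tips. Between 2 and 4 weeks 109 loci were higher at both, against 7.90 for independent lists, and 30 lower at both, against 5.68. Loci higher at 2 and lower at 4 weeks numbered 12, against 4.70, and the reverse 23, against 9.54. Between 4 and 12 weeks 98 were higher at both, against 14.6, and 5 and 7 went opposite ways, against 4.52 and 7.70. Opposite moves thus also exceeded independence in some pairs of weeks, so independent lists are no strict reference. The weeks share no library, but both medians describe loci picked for their differences.

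**Figure D3:**
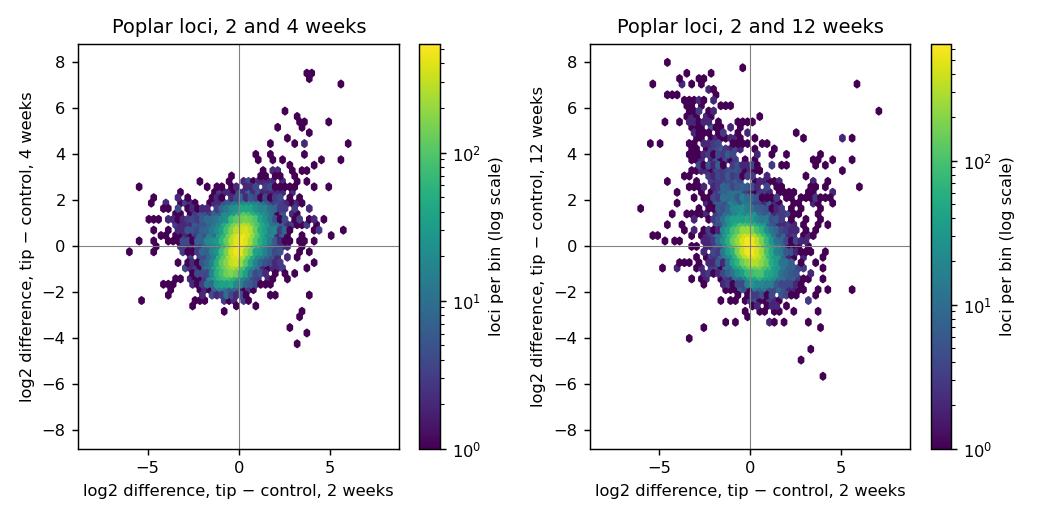
Each panel counts poplar loci (colour, log scale) by their log2 difference, root tip minus control root, at 2 weeks on the horizontal axis and at 4 or 12 weeks on the vertical axis, for 19709 loci with a mean of at least 5 CPM. Across loci the correlation is 0.359 for 2 and 4 weeks and −0.367 for 2 and 12 weeks. For 4 and 12 weeks, not drawn, it is 0.0601 (Spearman −0.0767).

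More loci passed the 4-fold rule between any 2 ages of 1 tissue (1592 to 3799) than between root tips and control roots of 1 age (953 to 1299). In control roots, 1149 loci were at least 4-fold higher and 1557 at least 4-fold lower at 12 than at 2 weeks, and in root tips 1816 and 1983. Scaled by library totals alone, the differences between root tips and control roots counted 459 and 826 loci at 2 weeks, 474 and 455 at 4 weeks, and 851 and 455 at 12 weeks, with median log2 differences of −0.18, −0.02 and −0.21 in place of −0.01, 0.10 and −0.03. The trend test left 1 residual degree of freedom and leaving out a week leaves none.

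The last comparison asked which fungal genes change over the 3 stages of root tips. Of 7252 Laccaria models tested, 0 changed with contact time at an adjusted p under 0.05 in edgeR, and at an unadjusted p under 0.05 there were 183 upward and 187 downward, 370 together, where chance alone gives 363. DESeq2 called 25 up and 10 down, limma on log2(RPKM + 0.1) 10 and 31, and week on a linear scale 3 and 0. As ratios between single libraries, 1200 models were at least 4-fold higher and 622 at least 4-fold lower at 4 than at 2 weeks, and 565 and 1140 at 12 than at 4 weeks. MiSSP8 went from 80.4 CPM at 2 weeks to 23.8 and 16.8 at 4 and 12 weeks, and MiSSP7 from 385 to 470 and 280. The test had 1 residual degree of freedom. Among 7252 genes it recovered 0 of 100 simulated changes that reached 16-fold at 12 weeks and grew by less than that from 2 weeks. Its count thus says little about whether fungal genes changed.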

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

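In this part, the comparison of label swaps within weeks was chosen after its result was seen; the tests of the opposite differences, thinning included, were added after the data were seen.

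The change of the poplar difference between root tips and control roots with contact time was fitted directly, as an interaction with log2 weeks. With 1 library per tissue and week, contact time cannot be told apart from the pool sampled. The 1 residual degree of freedom measures departure from a line in log2 weeks and not variation between pools. In this fit the difference grew with each doubling of weeks in 804 loci and fell in 360, or 1164 together. Of the 18 loci called over all weeks, 2 also changed with time. In Potri.002G072600 (adjusted p 0.00396, edgeR) and Potri.003G210700 (adjusted p 0.0129) the fitted difference fell with log2 weeks, although both were higher in root tips at 3 of 3 weeks. Potri.002G072600 had 2, 10 and 37 control reads against 1244, 9887 and 787 in root tips, and Potri.003G210700 1, 27 and 48 against 412, 4257 and 420. Their 2-week ratios thus rest on 2 and 1 control reads. Both were singled out after their values were seen. Swapping tissue labels within weeks gives 4 arrangements; the real one called 1164 loci and the highest other 509, and 1 of 4 had as many, which is too few for a share under 0.05. In simulated data with 28996 genes this test recovered 8 of 100 changes in which the difference reached 16-fold at 12 weeks. The simulated growth from 2 weeks was smaller than 16-fold.

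Over 19709 loci the differences at 2 and 12 weeks ran opposite, with a correlation of −0.367 (bootstrap interval −0.394 to −0.339; Spearman −0.328), although 62 loci were at least 4-fold higher at both weeks against 13.6 for independent lists. A length bias is argued against, since within 10 bins of locus length the median correlation was −0.3674 (lowest bin −0.463, highest −0.262). For lower depth of the 12-week root tip library, every library was thinned to 6430464 reads, which gave −0.354. The 2 differences share no library, so counting noise pulls their correlation toward 0, and thinning left the 12-week root tip library as it was. Thinning thus cannot decide whether a fault of that library plays a part. A swap of labels at 12 weeks is argued against because 35 of 35 loci called higher from weeks 2 and 4 alone, or 100%, were also higher at 12 weeks. Another explanation is that 12-week root tips lie further along the change of control roots from 2 to 4 weeks. The correlation was 0.0267 (bootstrap interval over loci 0.0088 to 0.0438), under the bound of 0.05 set for arguing against it. Spearman's rho was 0.0981, above that bound, so the explanation is not settled. Other differences of age, such as between the 2-week difference and the control change from 4 to 12 weeks (0.309), or of colonisation stage may be involved and were not tested against variation between pools.

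With 10 splits of the 6 poplar libraries into equal groups, a share under 0.05 is not possible. The real split called 17 higher loci and the highest other 0; for lower loci the real split called 1 and the highest other 0.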

How the results depend on the processing

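The number of poplar loci changing with time (1164) stayed within 1.5 times under its 8 alternatives (907 to 1534).

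Poplar loci higher and lower over all weeks (17 and 1) were 143 and 19 with DESeq2, 56 and 2 with no filter, 6 and 0 with unique reads, 1 and 0 with limma on log2(RPKM + 1) and likewise with 0.1, and 0 and 0 without the week block. Leaving out 1 week gave 0 to 253 and 0 to 13. Laccaria models higher and lower than mycelium (0 and 9) were 320 and 92 with DESeq2, 145 and 106 with no filter, 116 and 4 with limma on log2(RPKM + 1), and 229 higher with 0.1. Leaving out 1 library gave 0 to 178 and 0 to 98. Laccaria models changing with time (0) were 35 with DESeq2, 5 with no filter, 2 with unique reads, 2 and 41 with limma (1 and 0.1), and 3 with week on a linear scale. The cause was not tested in any of these, except that fewer libraries enter when a week is left out.

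For single weeks, a minimum of 100 reads gave 321, 316 and 646 higher and 357, 148 and 142 lower poplar loci at 2, 4 and 12 weeks, and a 2-fold rule 2491, 4146 and 2655 higher and 2646, 3206 and 2809 lower. For Laccaria the 100-read minimum gave 272, 1126 and 413 higher and 482, 864 and 1057 lower, the 2-fold rule 1585, 3497 and 1972 higher and 2363, 3249 and 2815 lower, and library totals alone 2910, 5849 and 2976 higher and 115, 158 and 223 lower. Fewer or more genes qualify by construction under the first 2 settings.

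The Laccaria share (7.45, 15.6 and 10.3%) was 15.2, 30.6 and 20.1% with unique reads, 4.15, 12.0 and 6.33% without the 10 most abundant genes, and 4.54, 12.6 and 7.60% without the 2 models with most mycelium reads, a setting added after seeing the data. The correlation of poplar differences at 2 and 12 weeks was −0.470 over 4435 loci with at least 50 CPM, also added.

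Of the named genes, the listed aquaporin of 939 bases reversed to 0.19 and 0.22 with limma on log2 RPKM (1 and 0.1). MiSSP7 ranged from 9.42 to 11.25 over 11 alternatives and passed in 6 (adjusted p 1.27e-11 to 0.313); MiSSP8 passed in 5 of 11 (0.000542 to 0.313). Potri.007G083300 passed in 6 of 11, Potri.010G000200 in 8 of 11 and Potri.015G101700 in 5 of 8, each with its direction kept, and so did the Laccaria models 295242 and 671638 in 8 of 11. Over all named genes, 80 values kept direction and side of the threshold, 28 passed it where the main test did not, 17 missed it and 2 reversed. Set tests of gene lists were not run, as the lists by product name could not be matched and those by ID had 2 and 3 tested members. Depth limits the 12-week root tips most.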

Other observations

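The tests in this part on Laccaria reads at poplar loci and on the length of Laccaria models were chosen after the results were seen; that on unique reads was not.

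Reads shared between neighbouring copies may account for part of the grouping of the 200 poplar loci of lowest p on the higher side. With unique reads alone, the 200 loci held 17 neighbouring pairs, 5.35 times the random mean of 3.18, against 11.6 times with all reads; on the lower side the ratios were 3.49 and 2.88. Sharing as the whole source is thus argued against. Unique reads also leave out reads shared between isoforms of the same locus, and the loci drawn from fell from 28022 to 20492. The fall from 11.6 to 5.35 times can thus not be put down to neighbouring copies alone. Copies that respond alike and 1 transcript split over several models stay open, since neither was tested.

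Laccaria reads assigned to poplar loci are a candidate explanation for poplar loci with few reads in control roots. With each library thinned to 6430464 poplar reads, 18 loci had at least 30 thinned reads over the 3 root tip libraries and at most 3 over the 3 control libraries, and 8 loci the reverse; 4 of the 17 loci that rose were among those with at most 3 control reads. From 2 to 4 weeks the level of the 17 loci in root tips changed by a median of 2.56 on the log2 scale (lowest locus 1.17, highest 4.50), and the ratio of Laccaria to poplar reads by 1.19. The median gap between them was 1.37, and 10 of the 17 loci lay over 1 unit away. A fungal gene can itself change between weeks, so this cannot be told apart from a poplar response without poplar counts of the mycelium, which were not used here.

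A hypothesis that short Laccaria models, such as those of small secreted proteins, are higher in root tips at every week was tested and not borne out for the median model. Models of at most 900 bases had a median log2 difference from mycelium that lay above that of longer models at 2 weeks (gap 0.40, bootstrap interval over models 0.32 to 0.47), below it at 4 weeks (gap −0.8451, −0.95 to −0.73) and at 12 weeks the gap was −0.03 (−0.13 to 0.09), or −0.41 (−0.57 to −0.14) among models with at least 50 CPM. The spread of short models was not tested; at 2, 4 and 12 weeks, 12.0, 14.2 and 17.7% of them were at least 4-fold higher and 7.38, 20.1 and 17.4% at least 4-fold lower, against 5.12, 17.6 and 11.7% and 6.76, 7.43 and 14.5% of longer models. Tests fixed beforehand of why short models would be higher were void for this reason and are not reported.

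Differences at one week were also set against the change of control roots between the other weeks, pairs that share no library. Over 19709 loci the correlation was 0.309 for the 2-week difference and the change from 4 to 12 weeks (Spearman 0.354), 0.109 for the 4-week difference and the change from 2 to 12 weeks (Spearman 0.132), and 0.0267 for the 12-week difference and the change from 2 to 4 weeks (Spearman 0.0981).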
